A study of Mus musculus with 5 samples.

How the data were processed

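Gene expression was measured by RNA-seq in 5 libraries of sorted mouse bone marrow HSCs, 3 control and 2 labelled Tle1/3/4-deficient, with groups and replicate numbers taken from the sample titles. The deposited table gives FPKM per gene symbol for 11643 genes, the unit being named with the deposited data; per the submitters' processing notes, the genome build was mm9 and the tools listed were TopHat and edgeR, with no version, role or order. The annotation, which tool computed FPKM and its filters are not given in the sources used here. FPKM divides by gene length and library total, so a few very abundant genes lower all others in that library. The table holds symbols without coordinates, and an mm9 annotation was not used here, so no positions are given. Mitochondrially encoded genes were not analysed here.

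Genes with a mean of at least 1 FPKM over the 5 libraries (10570) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, group as the only term, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of genes with low values. Genes are named in the text by a rule set before the data were examined: TLE family genes; up to 12 genes per direction past the threshold with non-overlapping groups and a higher group mean of at least 2 FPKM; for each list, members past the threshold and otherwise the 2 most highly expressed; and 8 genes that check the sort. Some genes the rule names are not reported here. Others are members that passed when adjusted over their list alone, or were chosen after their values were seen, which is not always repeated beside them. Of the 31 lists fixed from general knowledge of haematopoiesis, 27 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation as the alternative. Some genes (26) stand on several lists.

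The table includes exact values of 0 for genes that every cell uses. Rpl41 is listed at 0 in control replicate 1 and at 3509 to 7733 FPKM in the other libraries, and Eif4a1 at 0 in control replicate 2 and at 533 FPKM or more in the others. A value of 0 can therefore be a failed estimate, and such genes are given by library, with no fold against a group at 0. Genes at 0 numbered 1438, 1221 and 656 in control replicates 1, 2 and 3 and 1346 and 968 in deficient-labelled replicates 1 and 2.

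Total reads are unknown. Relative depth was estimated from the commonest ratio of low values (under 0.3 FPKM) between libraries, within a tolerance of 0.5%. Support was thin, with 10.0% to 34.0% of the low genes at that ratio, 8 of 65 for deficient-labelled replicate 2 against control replicate 1 and 4 of 38, the fewest genes, for control replicate 3 and deficient-labelled replicate 2. Direct and indirect ratios disagreed by at most 0.525%. The deepest library was 1.46 times the shallowest. No interval for counting error can be given. Spearman correlations between libraries across genes were 0.794 to 0.855, and the median SD of log2(FPKM + 1) over genes was 0.526 in the controls and 0.469 in the deficient-labelled libraries.

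The test was checked on 10178 genes simulated from the control means and limma's moderated spread, which draws each gene's variance toward the trend over genes. In the simulation 200 genes were changed, and a list of 30 others was shifted by 1. The test called 84 genes, of which 4 were unchanged. Camera found the shifted list (adjusted p = 1.84e-09) and none of 21 unshifted lists. The simulated genes varied independently of one another, so this check does not cover lists whose members vary together. In the real data the estimated correlation was 0.658 for the granulocyte-monocyte list, far above the preset. Alternatives covered the pseudocount, the filter on low values, median-of-ratios scaling and quantile normalization, eBayes without trend or with robust fitting, array weights, the replicate number as a block, other thresholds and leaving out each library. After the data were seen, a run without genes under 0.1 FPKM in 1 library and at 10 FPKM or more in another was added. Whether a gene overlaps another annotated gene was looked up by symbol in a GENCODE annotation of a later mouse build, which matched 99.6% of genes. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these look-ups and the plots.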

Results

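RNA was sequenced from haematopoietic stem cells (HSCs) sorted from the bone marrow of C57BL/6 mice as lineage-negative, c-Kit-positive, Sca-1-positive, CD150-positive and CD48-negative cells. The 5 libraries comprised 3 from control mice and 2 from mice labelled as deficient. In the latter, floxed alleles of Tle1, Tle3 and Tle4 were to be excised by Vav-Cre, a recombinase active throughout the blood system. That the alleles were excised is taken from the labels. TLE proteins are co-repressors that bind DNA through partner transcription factors such as the TCF, RUNX and HES families. The comparison was designed to ask how loss of Tle1, Tle3 and Tle4 alters gene expression in HSCs. Expression was given in FPKM (fragments normalised to transcript length and library size) for 11643 genes, of which 10570 had a mean of at least 1 FPKM and were tested. The columns summed to 616738, 642481 and 650087 FPKM in control replicates 1, 2 and 3, and to 683822 and 599137 FPKM in the deficient-labelled replicates 1 and 2. Absolute depth is unknown. Relative to control replicate 1, the depth estimated from few low values was 1.11 and 1.46 in control replicates 2 and 3, and 1.11 and 1.29 in deficient-labelled replicates 1 and 2. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

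Of the targeted genes, Tle3 went against the label. It stood at 4.35 ± 1.65 FPKM in the controls (SD, n = 3) and at 32.3 and 31.6 FPKM in the libraries labelled Tle1/3/4-deficient. The log2 fold change of 2.68 (SE 0.58) on the log2(FPKM + 1) scale did not pass over all genes (limma, adjusted p = 0.424). Tle4 was at 0.353 and 0.203 FPKM in the deficient-labelled libraries and at 5.67, 0.0129 and 5.29 FPKM in the controls. Control replicate 2 was thus lower than either (log2 fold change -1.45, adjusted p = 0.726). Tle1 was low throughout, at 1.99 ± 1.27 FPKM in controls (SD, n = 3) and 2.84 and 4.37 FPKM in the deficient-labelled libraries (adjusted p = 0.83). A gene-level FPKM includes exons outside the floxed part, so these values neither establish nor exclude the deletion, and every direction given here rests on the labels. The relatives Tle2 and Tle6 differed between groups by less than the SD of the controls, though by more than that of the deficient-labelled libraries. Tle2 was at 21.3 ± 8.95 against 15.3 ± 3.06 FPKM (adjusted p = 0.861). Tle6 was at 34.0 ± 10.8 against 24.8 ± 7.88 FPKM (SD, n = 3 and 2, adjusted p = 0.81).

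**Figure D1:**
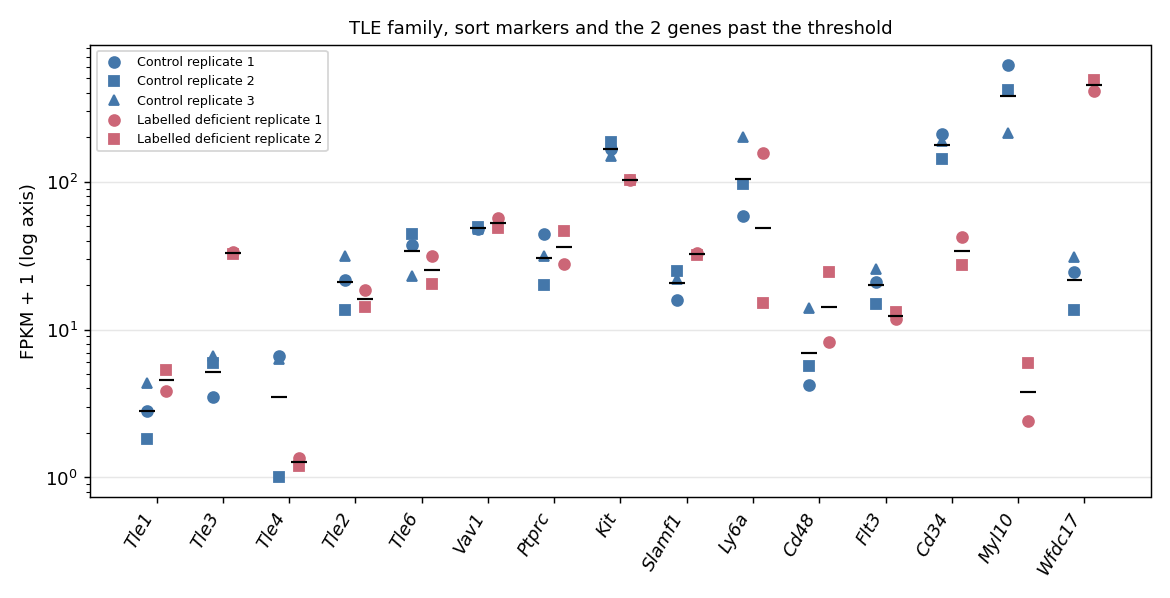
FPKM + 1 on a log axis for TLE family genes, sort markers and the 2 genes past the threshold, with 1 point per library (blue, control; red, labelled deficient) and a bar at each group's mean on the log scale. Tle3 lies at 32.3 and 31.6 FPKM in the deficient-labelled libraries, above every control, and Cd34 at 41.7 and 26.5 FPKM, below every control.

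The genes behind the sort were expressed in both groups. Kit, the stem cell factor receptor used in the gate, was at 166 ± 18.2 FPKM in controls and 102.0 ± 0.489 in the deficient-labelled libraries. Slamf1, which encodes CD150, was at 19.97 ± 4.66 and 31.4 ± 0.516 FPKM (SD, n = 3 and 2). Neither passed (adjusted p = 0.515 and 0.69). Ly6a, which encodes Sca-1, ranged from 57.8 to 199 FPKM in controls and was 155 FPKM in deficient-labelled replicate 1 but 14.0 FPKM in replicate 2. Cd48, whose product the gate excluded, was at 3.22 to 13.0 FPKM in controls and at 7.19 and 23.4 FPKM in deficient-labelled replicates 1 and 2 (limma, adjusted p = 0.737). In deficient-labelled replicate 2, Ly6a thus lay below every control and Cd48 above every control, against the direction of the gate. Cd34, a surface glycoprotein gained as HSCs become progenitors, was at 179 ± 35.4 FPKM in controls against 34.1 ± 10.7 (log2 fold change -2.38, SE 0.33). It passed when adjusted over the list alone (multipotent progenitor and lymphoid priming genes, adjusted p = 0.00125) and not over all genes (adjusted p = 0.208). Flt3 was at 19.6 ± 5.47 against 11.5 ± 0.967 FPKM, Ptprc at 31.1 ± 12.3 against 36.2 ± 13.2, and Vav1 at 47.7 ± 0.824 against 51.6 ± 5.81. None of these 3 passed (adjusted p = 0.719, 0.915 and 0.942).

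Past the threshold over all genes were 2 of 10570, 1 in each direction. Wfdc17, a small secreted protein with a whey acidic protein domain that is made by myeloid cells, rose from 22.03 ± 8.76 to 449 ± 58.4 FPKM (SD, n = 3 and 2; log2 fold change 4.36, SE 0.40, adjusted p = 0.0372). Myl10, a regulatory myosin light chain, fell from 415 ± 200 to 3.16 ± 2.49 FPKM (log2 fold change -6.66, SE 0.55, adjusted p = 0.0366). Both directions follow labels that Tle3 went against. At an unadjusted p under 0.05 there were 893 genes, 345 higher and 548 lower, where 528 would pass by chance. In 2754 genes (26.1%) the groups did not overlap, against 20% by chance. Myl10 and Wfdc17 lost their calls when any library other than control replicate 3 was left out. Their log2 fold changes stayed large when each library was left out, at -7.31 to -6.01 for Myl10 and 4.025 to 4.62 for Wfdc17. The adjusted p was 0.107 and 0.114 without control replicate 1, and 0.138 and 0.131 without control replicate 2. It was 0.217 and 0.223 without deficient-labelled replicate 1, and 0.198 and 0.342 without replicate 2. In data simulated with limma's moderated spread, the test recovered 0% of genes changed by 1 on the log2 scale. It recovered 28.4% of those changed by 2 and 92.4% of those changed by 4. The changed genes were drawn only from better-expressed genes, and failed estimates at 0 were not simulated, so recovery elsewhere may differ.

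Gene lists fixed before the data were examined were compared with all other genes. With the preset correlation of 0.01 between genes, 8 of 27 lists passed (camera), 6 shifted upward and 2 downward in the deficient-labelled libraries. With an estimated correlation none passed and the lowest adjusted p was 0.747. That version relies on the 3 residual degrees of freedom of the fit, so it had little power. G2/M genes, with an estimated correlation of only 0.0733, had an unadjusted p of 0.0626 (camera), against 2.97e-06 with the preset. Failing that version therefore does not show that a list did not shift. The 8 lists were granulocyte-monocyte, megakaryocyte-platelet, erythroid, G2/M, interferon-stimulated and immediate early genes (upward), and HSC-associated and cytosolic ribosomal protein genes (downward). No list member passed over all genes in this run. The median log2 fold change of all tested genes was -0.10 as deposited and 0.015 after median-of-ratios scaling, against which each list median can be read.

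**Figure D2:**
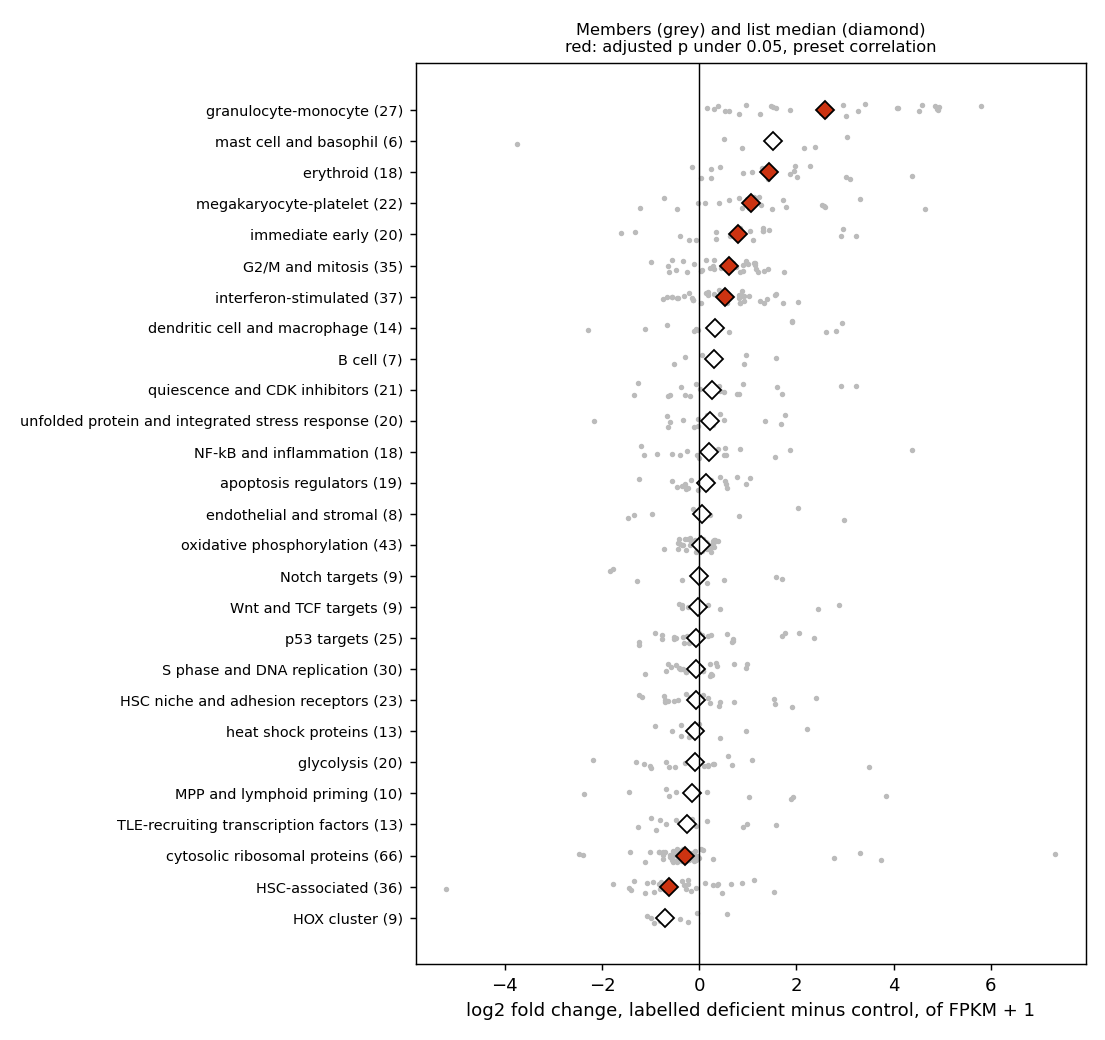
Log2 fold change, labelled deficient minus control, of each tested member (grey points) and the median (diamonds) of 27 gene lists, with the number of tested members in brackets and red marking lists at an adjusted p under 0.05 with the preset correlation. The granulocyte-monocyte median is 2.59 and the HSC-associated median -0.62.

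All 27 tested granulocyte-monocyte genes had positive fold changes, with a median of 2.59 (camera, adjusted p = 6.39e-13; adjusted p = 0.747 with an estimated correlation). Of these, 9 passed when adjusted over the list alone. S100a8, a calcium-binding alarmin of neutrophils, was at 988 ± 723 FPKM in controls and at 7679 and 37600 FPKM in deficient-labelled replicates 1 and 2. Its adjusted p over the list alone was 0.0336. Its partner S100a9 was at 216 ± 157 FPKM against 1219 and 11347. The granule genes Ngp and Camp were at 848 and 5850, and at 748 and 6283 FPKM, in the same 2 libraries. Ltf, Lcn2, Cebpe, Ly86 and Ly6c2 also passed over the list alone. The primary granule enzymes, chosen after their values were seen, differed among themselves. Mpo was at 1.15 FPKM in deficient-labelled replicate 1 and 958 FPKM in replicate 2, and Elane at 0.985 and 1293 FPKM. In the controls Elane was at 1.013, 35.0 and 36.2 FPKM. Prtn3, another such protease, was at 280 to 411 FPKM in the controls and at 450.0 and 468 FPKM in the deficient-labelled libraries. These are transcripts of mature neutrophils, which the lineage gate should remove, and of their precursors, which the Sca-1 and CD150 gates should remove. S100a8 also varied among the controls from 222 to 1657 FPKM. Without deficient-labelled replicate 2 the list median was 0.62 and the call was lost, and without replicate 1 the median was 5.02. Both runs kept only 1 deficient-labelled library, so they show the size of the shift in that library and not its significance. Directions again follow the labels that Tle3 went against.

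Erythroid genes had a median log2 fold change of 1.42, 17 of 18 being positive (adjusted p = 2.4e-06; adjusted p = 0.747 with an estimated correlation), and none passed over the list alone. The 2 most highly expressed, Car2 and Nfe2, did not pass, at 979 ± 162 against 991 ± 120 FPKM and 239 ± 27.0 against 281 ± 37.9 FPKM. Of 2 genes chosen after their values were seen, Klf1, an erythroid transcription factor, was at 3.94 ± 1.28 FPKM in controls and 15.04 and 94.4 FPKM in deficient-labelled replicates 1 and 2. Epor, the erythropoietin receptor, was at 15.4 ± 8.19 against 64.0 and 47.8 FPKM. Without deficient-labelled replicate 2, in which the granulocyte genes were also highest, the erythroid median was 0.59 and the call was lost (adjusted p = 0.306).

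**Figure D3:**
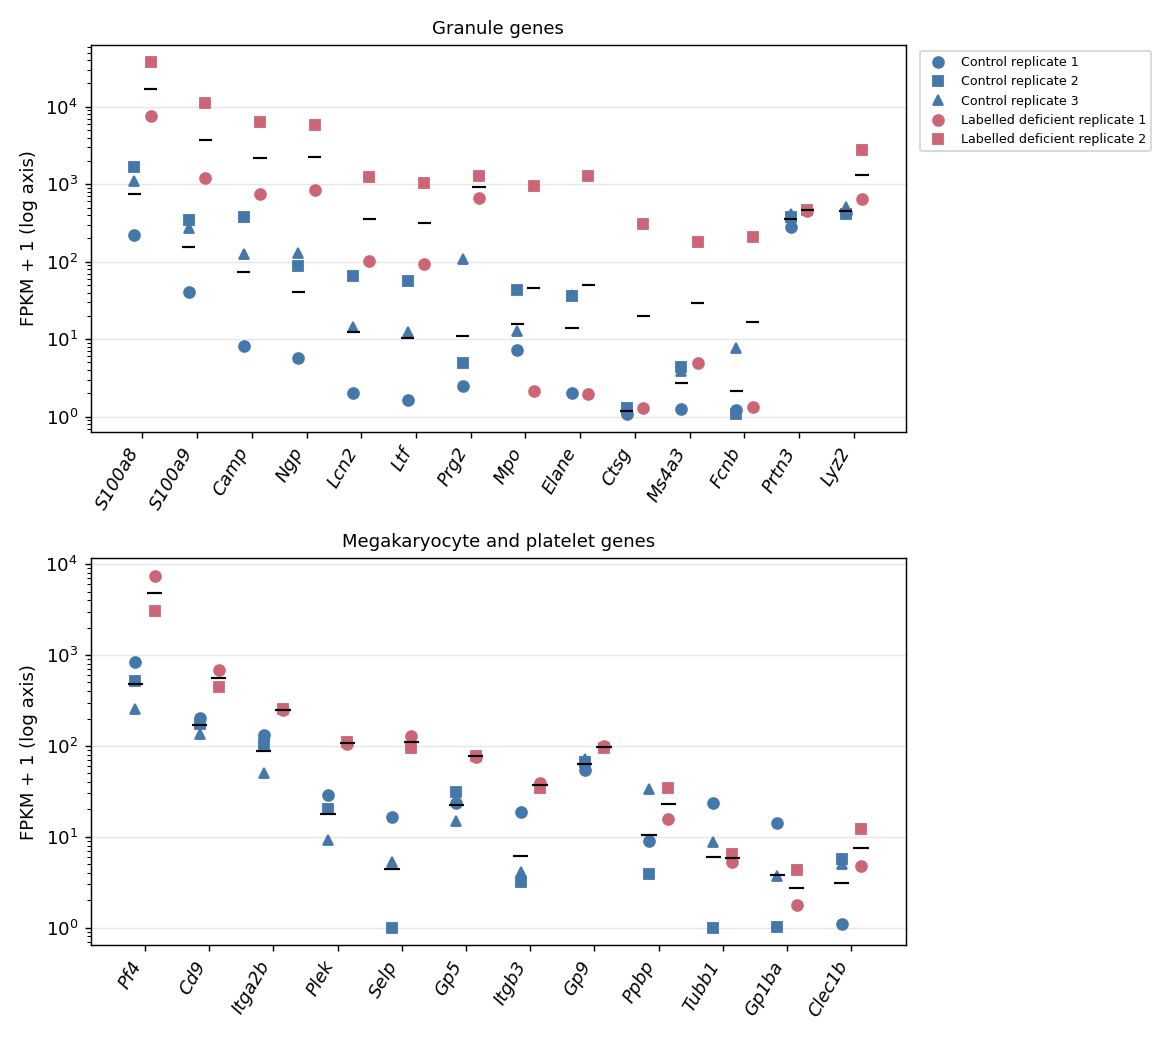
FPKM + 1 on a log axis for granule genes (top) and megakaryocyte and platelet genes (bottom), with 1 point per library and a bar at each group's mean on the log scale. Mpo lies at 1.15 and 958 FPKM in the deficient-labelled libraries, while Itga2b lies at 245 and 251 FPKM, above every control.

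Megakaryocyte and platelet genes had a median log2 fold change of 1.07, with 18 of 22 positive (adjusted p = 7.94e-08; adjusted p = 0.747 with an estimated correlation). Of these, 7 passed when adjusted over the list alone. Pf4, a platelet alpha-granule chemokine, was at 535 ± 293 FPKM in controls and 7503 and 3023 FPKM in the deficient-labelled libraries (list alone, adjusted p = 0.00671). Cd9 was at 170 ± 34.1 against 570 ± 173 FPKM, and the integrin Itga2b (CD41) at 95.1 ± 42.1 against 248 ± 4.39. Gp5 was at 22.2 ± 7.99 against 75.7 ± 1.004, and Plek, a platelet protein kinase C substrate, at 18.6 ± 9.91 against 105 ± 3.84 FPKM (SD, n = 3 and 2). Selp, at 129 and 92.85 FPKM in the deficient-labelled libraries, was at 15.5, 0 and 4.33 FPKM in the controls, and Itgb3 was at 7.64 ± 8.71 against 35.9 ± 3.50 FPKM. Other members, chosen after their values were seen, did not pass. Tubb1 and Gp1ba, both abundant in platelets, were at 4.22 and 5.53, and at 0.785 and 3.26 FPKM, in the deficient-labelled libraries. In the controls they were at 22.6, 0 and 7.81, and at 13.3, 0.0233 and 2.74 FPKM. Ppbp and Clec1b had positive log2 fold changes, of 1.12 and 1.28. The list kept its call without each control library in turn. Its median was 1.46 without deficient-labelled replicate 1 and 1.04 without replicate 2, each run keeping only 1 deficient-labelled library.

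G2/M and mitosis genes had a median log2 fold change of 0.62, 27 of 35 being positive and 15 above every control in both deficient-labelled libraries (adjusted p = 2e-05; adjusted p = 0.747 with an estimated correlation). None passed over the list alone. Cks2, a subunit of cyclin-dependent kinase complexes, was at 227 ± 42.1 against 345 ± 6.96 FPKM, and Birc5 (survivin) at 138 ± 9.92 against 204 ± 5.74 FPKM (SD, n = 3 and 2). Among members chosen after their values were seen, Cdk1 was at 36.9 ± 0.480 against 73.3 ± 14.6 FPKM and Ccnb1 at 40.3 ± 6.09 against 79.3 ± 12.9 FPKM. The call held without each control library in turn, with a median of 0.36 without control replicate 1. The median was 0.63 without deficient-labelled replicate 1 and 0.50 without replicate 2, each run keeping only 1 deficient-labelled library. Genes of S phase and DNA replication did not pass (median -0.069, 12 positive and 18 negative of 30, adjusted p = 0.883). Mcm6 was at 276 ± 29.2 against 218 ± 11.1 FPKM and Pcna at 225 ± 47.0 against 185 ± 23.6 FPKM.

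HSC-associated genes had a median log2 fold change of -0.62, with 27 of 36 negative and 12 below every control (adjusted p = 0.00626; adjusted p = 0.754 with an estimated correlation). Ndn (necdin), a growth suppressor expressed in HSCs, was at 44.7 ± 15.4 FPKM in controls and at 0.162 and 0.205 FPKM in the deficient-labelled libraries. It passed over the list alone (adjusted p = 0.00125) but not over all genes (adjusted p = 0.0736), where it passed only with robust eBayes (adjusted p = 0.0332) and without on-off genes (adjusted p = 0.0097). That last run dropped genes under 0.1 FPKM in 1 library and so kept Ndn. By a cut of 0.5 FPKM Ndn is itself an on-off gene, so the run does not test whether its call survives their removal. Its annotated locus overlaps another gene. The most highly expressed members were Ifitm3, at 1337 ± 270.5 against 1884 ± 1037 FPKM, and Ifitm1, at 1708 ± 846 against 928 ± 157 FPKM. Members chosen after their values were seen were Cdkn1c, a cyclin-dependent kinase inhibitor, at 44.6 ± 3.39 against 17.1 ± 2.65 FPKM, and Hlf, an HSC transcription factor, at 23.1 ± 3.24 against 8.07 ± 2.68 FPKM. Gata2 and Gfi1b lay the other way, at 152 ± 32.5 against 208 ± 20.1 and 63.5 ± 19.8 against 115 ± 21.6 FPKM. Without deficient-labelled replicate 2, in which granulocyte genes were highest, the median was -0.35 and the call was lost (adjusted p = 0.492).

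For 3 further lists, single libraries decided the call. Interferon-stimulated genes had a median of 0.53, 26 of 37 being positive (adjusted p = 0.00218; adjusted p = 0.769 with an estimated correlation). It was -0.36 without deficient-labelled replicate 1 (adjusted p = 0.264) and 1.203 without replicate 2. Ly6e was at 368 ± 23.4 FPKM in controls and 623 and 380 FPKM in the deficient-labelled libraries, Psmb8 at 415 ± 32.8 against 578 and 311 FPKM. Immediate early genes had a median of 0.81, 15 of 20 being positive (adjusted p = 0.00762; adjusted p = 0.756 with an estimated correlation). It was -0.27 without deficient-labelled replicate 2 (adjusted p = 0.674), 1.66 without replicate 1, and 0.53 without control replicate 1 (adjusted p = 0.0526). Junb, an AP-1 subunit, at 47.8 ± 2.69 against 124 ± 41.3 FPKM, and the anti-proliferative gene Btg2, at 6.96 ± 4.42 against 66.2 ± 54.5 FPKM, passed upward over the list alone. The phosphatase Dusp2 passed downward, at 103 ± 9.74 against 33.2 ± 6.13 FPKM. Dusp1 was at 15.1 and 365 FPKM and Ier2 at 99.95 and 354 FPKM in deficient-labelled replicates 1 and 2. Cytosolic ribosomal protein genes had a median of -0.30, 58 of 66 being negative (adjusted p = 0.00218; adjusted p = 0.798 with an estimated correlation). Rps28 was at 12731 ± 3260 against 4667 ± 499 FPKM and Rpl13 at 6340 ± 122 against 4787 ± 1538. That median was 0.037 without deficient-labelled replicate 2 (adjusted p = 0.579) and -0.66 without replicate 1. The call was also lost without control replicate 2 (adjusted p = 0.0726) or 3 (adjusted p = 0.177), and with eBayes without trend (adjusted p = 0.0504). Some members, such as Rpl41 and Rpl32, are listed at 0 in 1 or 2 libraries.

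Lists of direct relevance to TLE partners did not pass, but their coverage was partial. Tested were 9 of 25 Wnt and TCF targets, 9 of 18 Notch targets and 13 of 20 TLE-recruiting transcription factors. Axin2, Tcf7 and Lef1 were not among them, so a change in such genes cannot be judged. Wnt and TCF targets had a median of -0.017 (4 positive and 5 negative, adjusted p = 0.425), Notch targets -0.0028 (adjusted p = 0.883) and TLE-recruiting transcription factors -0.25 (4 positive and 9 negative, adjusted p = 0.531). Myc, a target on both the Wnt and the Notch list, was at 220 ± 90.0 against 165 ± 37.3 FPKM and Mycn at 134 ± 57.5 against 107 ± 11.1. Hes6 was at 73.8 ± 11.2 against 115 ± 66.9 FPKM. Of the recruiting factors, Myb was at 83.6 ± 23.5 against 41.7 ± 15.6 FPKM and Hhex at 88.0 ± 29.95 against 48.0 ± 23.4 FPKM. Neither passed (adjusted p = 0.548 and 0.622). HOX cluster genes had a median of -0.71, 8 of 9 being negative (adjusted p = 0.395). Hoxa9 was at 44.8 ± 7.10 against 21.4 ± 8.28 FPKM and Hoxb2 at 20.5 ± 13.1 against 18.3 ± 18.6.

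Markers of other cell types gave no further call with all libraries. Dendritic cell and macrophage genes had a median of 0.32 (adjusted p = 0.119). Bst2 was at 198 ± 16.1 against 144 ± 104 FPKM and H2-Ab1 at 55.2 ± 40.9 against 57.6 ± 19.7. The list passed upward without control replicate 1 (median 0.55, adjusted p = 0.011), and its median was 0.98 without deficient-labelled replicate 1 and 0.081 without replicate 2, neither passing. B cell genes had a median of 0.31 (adjusted p = 0.472). Cd37 was at 62.8 ± 8.35 against 85.4 ± 51.1 FPKM and Cd79b at 49.0 ± 9.11 against 42.3 ± 36.6. The B cell list had a median of 0.88 without deficient-labelled replicate 1 and -1.06 without replicate 2, each run keeping only 1 deficient-labelled library. Mast cell and basophil genes had a median of 1.51 (adjusted p = 0.395). Mitf, a transcription factor of mast cells, was at 9.40, 15.5 and 13.5 FPKM in the controls and at 0 and 0.0216 FPKM in the deficient-labelled libraries. It passed over the list alone (adjusted p = 0.00498). Endothelial and stromal genes had a median of 0.051 and a test pointing downward (adjusted p = 0.971). Eng was at 192 ± 39.2 against 81.4 ± 46.6 FPKM and Tie1 at 51.0 ± 17.8 against 25.5 ± 9.98. Multipotent progenitor and lymphoid priming genes had a median of -0.15 and an upward test (adjusted p = 0.82). Besides Cd34, Vpreb1, part of the surrogate light chain of B cell precursors, passed over the list alone, at 0, 0 and 0.0794 FPKM in controls and 4.70 and 37.1 FPKM in the deficient-labelled libraries. So did Il12a, at 21.5 ± 8.06 against 141 and 42.8 FPKM. The T and NK cell list had 4 tested members, too few for the test.

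Stress, survival and metabolic lists also gave no call. NF-kB and inflammation genes had a median of 0.20 (adjusted p = 0.306). Nfkbia was at 168 ± 39.5 against 164 ± 11.7 FPKM and Myd88 at 56.4 ± 5.12 against 83.1 ± 23.3. Il1b, an inflammatory cytokine at 0, 0 and 1.501 FPKM in controls and 16.0 and 46.4 FPKM in the deficient-labelled libraries, passed over the list alone (adjusted p = 0.0188). The median was 0.26 for quiescence genes (adjusted p = 0.395). Trp53 was at 297 ± 45.3 against 228 ± 26.6 FPKM and Txnip at 228 ± 28.4 against 145 ± 21.9. Apoptosis regulators had a median of 0.14 (adjusted p = 0.593), with Bax at 146 ± 8.63 against 178 ± 64.9. For p53 targets the median was -0.061 and the test pointed upward (adjusted p = 0.674), with Gpx1 at 1319 ± 116 against 1324 ± 188 FPKM. It was 0.23 for unfolded protein response genes (adjusted p = 0.287), with Hspa5 at 227 ± 49.2 against 253 ± 51.3. Heat shock genes had a median of -0.085 and a mean of 0.071 (adjusted p = 0.883), with Hspa8 at 1791 ± 20.1 against 1397 ± 220.2 FPKM. Niche and adhesion receptors had a median of -0.075 with an upward test (adjusted p = 0.971), with Cd47 at 358 ± 29.9 against 313 ± 24.0. Glycolysis genes had a median of -0.097 (adjusted p = 0.834). Ldha was at 658 ± 28.0 against 1054 ± 26.8 FPKM and Gapdh at 795 ± 127 against 849 ± 133. Oxidative phosphorylation genes had a median of 0.027 and a mean of -0.024 (adjusted p = 0.738), with Cox4i1 at 1113 ± 166 against 984 ± 219 FPKM. The list median was -0.27 without deficient-labelled replicate 1 and 0.34 without replicate 2, each run keeping only 1 deficient-labelled library. Wnt targets, with a mean of 0.51, also had a test pointing upward against a negative median.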

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

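The run without on-off genes was chosen after the data were seen; the other alternatives were planned. The count of 2 genes past the threshold was 0 with a pseudocount of 0.1 or 0.5, without the filter on low values and with array weights, 1 with eBayes without trend (Rab4b, with Wfdc17 and Myl10 both lost), 3 with quantile normalization, 4 with median-of-ratios scaling and without on-off genes, and 5 with robust eBayes or at an adjusted p under 0.10. Leaving out each library gave 0 to 5 genes. At a count of 0 the tool was limma throughout, and 893 genes had an unadjusted p under 0.05 in the reported run. With 1 deficient-labelled library left, that library is assumed to vary like the others. The replicate numbers do not pair the samples, since only 2 numbers are shared, the labels do not say what they mark and same-numbered libraries deviated with correlations of 0.0352 and 0.00687; with the replicate block, which leaves out control replicate 3 in effect and has few residual degrees of freedom, 22 genes passed, among them S100a8, S100a9, Ngp, Camp, Ltf, Lcn2, Ly6c2, Mt1 and Prg2, and the ribosomal protein list did not (adjusted p = 0.385). The count of 8 lists was 0 with an estimated correlation and ranged from 4 (without deficient-labelled replicate 2) to 9 when libraries were left out. The targeted genes Tle1, Tle3 and Tle4 kept direction and stayed short of the threshold in every alternative run that tested them. The filter at 5 FPKM left Tle1 and Tle4 untested. The cause of the other changes was not tested, and unknown depth leaves the error of low values unquantified.

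Leaving out each library in turn, log2 fold changes that changed sign ranged from -1.16 to 3.35 for Dusp1, -0.09957 to 6.02 for Fos, -1.41 to 0.49 for Gp1ba, -0.75 to 2.58 for Ifit1, -2.80 to 0.58 for Ly6a, -2.88 to 5.92 for Mpo, -1.002 to 3.68 for Mx2, -0.13 to 0.61 for Ptprc, -1.30 to 0.97 for Tubb1, -0.19 to 2.70 for Usp18, -0.00499 to 0.22 for Vav1. List medians that changed sign ranged from -1.06 to 0.88 for B cell, -0.27 to 0.02443 for HSC niche and adhesion receptors, -0.77 to 1.09 for MPP and lymphoid priming, -0.37 to 0.12 for Notch targets, -0.30 to 0.21 for Wnt and TCF targets, -0.66 to 0.03736 for cytosolic ribosomal proteins, -0.61 to 0.35 for endothelial and stromal, -0.21 to 0.05435 for glycolysis, -0.20 to 0.07727 for heat shock proteins, -0.27 to 1.66 for immediate early, -0.36 to 1.203 for interferon-stimulated, -0.27 to 0.34 for oxidative phosphorylation, -0.14 to 0.19 for p53 targets. Medians of lists without a call that stayed positive ranged from 0.001 to 0.27 for NF-kB, 0.046 to 0.48 for quiescence and 0.007 to 0.19 for apoptosis genes, and without deficient-labelled replicate 2 they were 0.038, 0.046 and 0.008. With the replicate block, values were 0.27 (Tubb1), 0.33 (MPP), 0.12 (Notch) and -0.27 (endothelial). Median-of-ratios scaling gave 0.071 (Tubb1), 0.043 (niche), 0.096 (Notch), 0.058 (S phase), 0.082 (Wnt), 0.031 (glycolysis), 0.043 (heat shock) and 0.064 (p53). Quantile normalization gave 0.11 (Tubb1), 0.024 (niche), 0.17 (Notch), 0.26 (Wnt), -0.021 (oxidative phosphorylation) and 0.028 (p53). A pseudocount of 0.1 gave 0.042 (Gp1ba), 0.91 (Tubb1), 0.019 (Wnt) and -0.031 (apoptosis), and a pseudocount of 0.5 gave 0.22 (Tubb1). The filter at 5 FPKM gave 0.16 (MPP), 0.17 (Wnt), -0.10 (apoptosis) and -0.55 (endothelial), and no filter 0.004621 (Notch). Array weights gave 0.063 (Wnt), -0.002979 (apoptosis) and -0.02018 (oxidative phosphorylation), and the run without on-off genes -0.02614 (NF-kB) and -0.12 (endothelial).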

Other observations

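The tests of explanations and the splits of the libraries in this part were chosen after the result was seen, except the count and the odds ratio of genes that overlap another annotated gene; the limma tests and the other scalings were planned.

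Several genes outside the lists, chosen after their values were seen, differed widely without passing over all genes in the reported run. Mt1, a metal-binding metallothionein, was at 15.8 ± 2.53 FPKM in controls and 140 ± 10.6 in the libraries labelled Tle1/3/4-deficient (SD, n = 3 and 2, adjusted p = 0.066). It passed with median-of-ratios scaling (adjusted p = 0.0489), robust eBayes (0.0332) and without on-off genes (0.0121). Tuba8, an alpha-tubulin, was at 30.3 ± 9.38 against 179 ± 23.6 FPKM (adjusted p = 0.208), and Plac8 at 166 ± 59.1 against 660 ± 231 FPKM and Gadd45g at 13.3 ± 7.36 against 88.9 ± 7.69 FPKM (adjusted p = 0.345 for both). Egfl7, a secreted factor of endothelial cells, was at 185 ± 16.6 against 55.9 ± 2.20 FPKM (adjusted p = 0.227). Prg2, the eosinophil major basic protein, was at 1.46, 3.89 and 107 FPKM in controls and 663 and 1295 FPKM in the deficient-labelled libraries (adjusted p = 0.424; 0.0135 without control replicate 3). Of 7 GIMAP GTPase genes, which act in lymphocyte survival, 6 had lower means in the deficient-labelled libraries and Gimap9 a higher one, the most abundant being Gimap1 at 239 ± 15.7 against 87.8 ± 36.1 FPKM and Gimap6 at 212 ± 30.7 against 112 ± 21.7 FPKM, and none passed (lowest adjusted p = 0.405). Within glycolysis the lactate dehydrogenase subunits went apart, Ldhb at 136 ± 10.8 against 67.3 ± 5.93 FPKM (adjusted p = 0.433) and Ldha the other way, and the glucose transporter Slc2a1 was at 32.9 ± 3.70 against 12.9 ± 4.07 FPKM (adjusted p = 0.465).

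The deficient-labelled libraries also differed from each other, in genes mostly chosen after their values were seen. The interferon genes Usp18, Ifit1 and Mx2 were at 168, 65.4 and 25.9 FPKM in replicate 1 and at 21.9, 5.60 and 0.0452 FPKM in replicate 2. The basophil and mast cell genes Hdc and Prss34 were at 0.0266 and 0.0579 FPKM in replicate 1 and at 35.9 and 24.4 FPKM in replicate 2, while Gzmb and Fcer1a of the same list went the other way, at 33.1 and 5.43 FPKM in replicate 1 and 1.30 and 0.175 FPKM in replicate 2. The B cell gene Cd79a was at 0 in replicate 1 and at 38.5 FPKM in replicate 2. Fos was at 4.67 and 394 FPKM.

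Tle3 stood higher in the deficient-labelled libraries, although it is a targeted gene. Neutrophil RNA as the source is argued against, since the ratio of replicate 2 to replicate 1 was 0.976 for Tle3 and 4.90 to 11.95 for the 6 granule genes S100a8, S100a9, Ngp, Camp, Ltf and Lcn2. Library scaling is also argued against, since the log2 fold change was at least 2.75 under the 2 other scalings. Exchanged group labels cannot be told apart, because Tle4 averaged 0.278 FPKM in the deficient-labelled libraries, below control replicates 1 and 3 and above replicate 2. The value in control replicate 2, 0.0129 FPKM, may be a failed estimate. An exchange would also put Tle1 and Tle4 above every control-labelled library, which neither met. Tle1 was at 2.84 FPKM in deficient-labelled replicate 1 and at 3.33 FPKM in control replicate 3. Transcripts that keep exons outside the floxed part may also contribute, which gene-level values do not test.

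Granulocyte genes stood higher in the deficient-labelled libraries. Scaling as the whole cause is argued against by a list median of at least 2.67 under the 2 other scalings. A share of neutrophil RNA that varies between sorts is consistent with the mean log2 level of the 6 granule genes, which ranged over 4.27 among controls and 3.06 between the deficient-labelled libraries, although the lineage gate should remove these cells. A single source for all granulocyte genes is not decided, since the criterion was revised more than once after all values were seen, and 1 version left it open. The ratio of replicate 2 to replicate 1 had a median of 724 over 6 primary granule genes. It was at least 45.6 for Mpo, Elane, Ctsg, Ms4a3 and Fcnb, which thus did not change in step with the 6 later granule genes (4.90 to 11.95). The size of these ratios is imprecise, because Mpo, Elane, Ctsg and Fcnb were at 0.294 to 1.15 FPKM in replicate 1. Prtn3, with a ratio of 1.04, was at 280 to 411 FPKM in the controls, so its ratio says little about a source. A difference in the HSCs themselves remains open and untested.

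Some genes were under 0.5 FPKM throughout 1 genotype label and at 10 FPKM or more throughout the other: Rab4b, at 0 in all controls and at 84.8 and 78.8 FPKM in the deficient-labelled libraries (adjusted p = 0.0525, and 0.0332 to 0.0493 under the 5 alternatives in which it passed), and Ndn, Sh2b3, Fam181b, Tmem237 and Pygm in the opposite direction. Chance cannot be excluded, since 8 of the 10 splits of the 5 libraries into 3 and 2, the real split included, gave at least 6 such genes, and the highest other split gave 14. Reads assigned to an overlapping gene may contribute, as 5 of the 6 overlap another annotated gene (Pygm does not), meeting the criterion of at least 5 set beforehand; that criterion took no account of the base rate, and against the 49.97% of other genes that overlap, a check added after the count was seen gave Fisher's exact p = 0.218. For 82 genes near 0 in a single library, 64.6% overlapped another gene (odds ratio 1.83, Fisher's exact p = 0.00989), which lies short of the odds ratio of 2 set beforehand and leaves that explanation open. Sh2b3, an adaptor that restrains cytokine signalling, was at 39.0, 18.5 and 21.5 FPKM in controls and at 0.112 and 0 FPKM in the deficient-labelled libraries, and needs a read-level check before it is read as biology.

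The count of 2 genes past the adjusted threshold does not exclude chance, since 6 of the 10 splits gave as many and the highest other split gave 6. At an unadjusted p under 0.05 the real split gave 893 genes, the highest other split 538, and 1 of the 10 splits as many, which are too few splits for a share under 0.05.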
